A study of Mus musculus with 12 samples.

How the data were processed

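Hippocampal RNA of 12 mice, 4 in each of 3 groups, was hybridised to the nCounter Mouse Neuroinflammation panel of 770 transcripts. The authors deposited 1 table of signal values, which per the labels are probe counts normalized with the geometric mean of 10 housekeeping genes, on a linear scale. None of these 10 genes is in the table used here, which holds 756 genes by symbol, and the software, its version and any background subtraction are not given in the sources used here. Of the symbols, 749 matched current mouse gene names and 7 matched as synonyms; no coordinates were used. Every value was a whole multiple of 1 factor per mouse (100% of values within 0.01 of a whole number), with factors from 0.871 to 1.10. They ran from 0.871 to 0.993 in non-transgenic, 0.946 to 1.10 in vehicle-treated 5xFAD and 1.03 to 1.09 in TPPU-treated mice. The deposited scaling therefore differed with group, and how far it sets the changes was not tested. The whole numbers were taken as probe counts; their totals of 1050334 to 1314362 per mouse set the counting precision, and the spread between mice set that of each comparison.

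Values were tested as log2 of the normalized count plus 1, for the 695 genes with a mean of at least 20 over the 12 mice, and the 61 genes under that minimum were left out. All 3 groups entered 1 linear model with limma 3.58.1 in R 4.3.3, with 9 residual degrees of freedom and a prior spread that follows the mean. The 3 comparisons were 5xFAD vehicle minus non-transgenic vehicle, 5xFAD TPPU minus 5xFAD vehicle and 5xFAD TPPU minus non-transgenic vehicle. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

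26 gene lists, of microglial states, complement, antigen presentation, interferon, phagocytosis, cytokines, astrocytes, lipid mediators, neurons, myelin, vessels, other immune cells, autophagy, DNA damage, epigenetic regulators, apoptosis and growth factors, were fixed before the data were examined, as were the comparisons, tests, filter and most of the other settings tried. 23 lists had at least 5 tested members and were tested with limma's fry, adjusted over the lists of a comparison. Oligodendrocyte progenitors (0 tested members), border-associated macrophages (3) and choroid plexus and ependyma (1, Ttr) were not tested. Some genes stand in several lists, so the lists are not independent. Camera, which compares a list with the rest of the panel, was run with a preset correlation of 0.01 and with an estimated correlation. Adjusted p values given with an estimated correlation are camera's. Fry compares a list with no other genes, so the tests ask different questions. The rest of a neuroinflammation panel is no neutral background for such lists. List scores per mouse were compared with exact two-sided permutation tests over 70 arrangements of 4 against 4 mice, adjusted over the scores.

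The genes named in the text were chosen by a rule. For each of the 2 main comparisons it took up to 15 called genes per direction with the largest change, or the 10 with the smallest p where fewer than 5 passed, the 3 most changed called members of each list (or up to 2 with the smallest p where none passed), and a fixed set of genes. For the comparison of TPPU-treated with non-transgenic mice, in which no gene passed, it took the 10 genes with the smallest p, 9 higher and 1 lower. Genes moved back by TPPU were taken from the genotype calls by the same kind of rule. Uty, Kdm5d, Ttr, Hspb1 and Trp73 lie outside the rule and were chosen after their values were seen. Some genes the rule took were left out for space.

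The sharing of the vehicle-treated 5xFAD mice by both changes was checked with 500 simulated data sets without effects, 200 with a genotype effect alone, and 6 ordered splits of the shared mice. The procedure was tested on simulated data: with 200 of 695 genes changed, limma recovered 59.7% of genes changed 1.5-fold, 85.5% of those changed 2-fold and 95.6% of those changed 3-fold, and 3.24% of its calls were false. Fry gave an unadjusted p under 0.05 in 4.5% of 200 simulated unchanged lists of 21 genes and in 100% of lists lowered by 0.66 log2. The limma draws used independent noise per gene and changes in both directions, and the fry lists were random genes. Estimated correlations in the real lists were 0.19 for interferon and 0.78 for plaque-associated genes, so these rates need not hold for them.

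Also tried were pseudocounts of 0.1 and 10, no filter and a minimum of 50, median centring, quantile normalization, other variance models (no trend, robust, sample weights), the mouse number as a block, fits of only the groups compared, and fits without each mouse in turn. Rescaling to the housekeeping genes was not run, since these are not in the table. Added after seeing the data were voom weights on the whole counts, Y-linked status as a block (Uty and Kdm5d both at least 200), fits without both mice with high Ttr, and centring on the epigenetic, DNA damage and autophagy genes.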

Results

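Hippocampal RNA of 12 mice was measured with the NanoString nCounter Mouse Neuroinflammation panel, in which coloured barcoded probes are hybridised to transcripts and counted one by one without amplification. The mice fell into 3 groups of 4: non-transgenic littermates given vehicle, 5xFAD mice given vehicle, and 5xFAD mice given TPPU. 5xFAD mice carry human transgenes with familial Alzheimer's disease mutations and develop amyloid plaques early in life. TPPU inhibits soluble epoxide hydrolase, the enzyme that turns epoxy fatty acids into diols. The dose was 3 mg/kg, taken with the drinking water from the age of 2 months over the next 2.5 months, and the vehicle was 1% polyethylene glycol. The table held 756 genes, of which 695 had a mean of at least 20 normalized counts and were tested. Total probe counts ranged from 1050334 to 1314362 per mouse, and the correlation between mice of a group, across genes that are not independent of each other, ranged from 0.960 to 0.991 over 18 pairs.

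The labels describe the mice as male. The Y-linked genes Uty and Kdm5d, named here after their values were seen, stood at 366 to 518 and at 306 to 369 normalized counts in 6 mice, 2 in each group. In the other 6 mice they stood at 15.2 to 33.5 and at 14.2 to 22.8. Such low values conflict with the male label for those 6 mice, so the mice cannot be taken as 12 males. Ttr, the choroid plexus transcript for transthyretin and likewise named after its values were seen, reached 16461 normalized counts in non-transgenic mouse 4 and 4270 in 5xFAD vehicle mouse 1, against 77.1 to 284 in the other 10 mice. Fits with Y-linked status as a block and without both mice with high Ttr were added after these values were seen; between the genotypes limma called 130 and 122 genes in them, all higher.

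The comparison of vehicle-treated 5xFAD mice with non-transgenic mice asked what the transgenes do to immune and glial transcripts at this age. The genes with the largest changes were genes of microglia and other myeloid cells, and each called gene was higher in 5xFAD mice. Ctse, a protease of myeloid cells, had the largest fold and rose from 28.9 ± 7.34 to 1005 ± 623 normalized counts (SD, n = 4 mice per group), 29.7-fold. Cst7, a cysteine protease inhibitor made by microglia at plaques, rose 16.5-fold from 14.1 ± 3.83 to 273 ± 143, and Clec7a, a pattern recognition receptor, rose 16.3-fold from 16.4 ± 6.10 to 326 ± 237. Mice with low Y-linked counts had Uty at 15.2 to 33.5 and Kdm5d at 14.2 to 22.8. The non-transgenic means of Ctse, Cst7 and Clec7a were near these levels. Background subtraction is not given in the sources used here, and how far background sets the size of these folds was not tested. The same holds for other genes with low non-transgenic counts. Trem2, the lipid-sensing microglial receptor, rose 8.04-fold from 287 ± 63.6 to 2405 ± 951, and its signalling adaptor Tyrobp rose 9.07-fold from 527 ± 45.7 to 5251 ± 2606. Limma called 130 of 695 genes higher and 0 lower at an adjusted p under 0.05, where 202 genes had an unadjusted p under 0.05, 195 of them higher and 7 lower. Of the 130 genes, 92 changed more than 2-fold. In 150 genes all 4 vehicle-treated 5xFAD mice lay above all 4 non-transgenic mice, and in 1 gene below them, where chance gives 2.86% of genes in both directions together.

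The scale of the arrays decided whether lower genes were called. The deposited scaling factors also differed, at 0.946 to 1.10 in vehicle-treated 5xFAD and 0.871 to 0.993 in non-transgenic mice. The median of all tested genes lay 0.13 log2 above 0 in this comparison. The array medians differed by 0.28 between the groups on average, so centring each array on its median lowered each change by 0.28, and all changes below are to be read against these shifts. Limma called 102 genes higher and 88 lower after each array was centred on its median, and 80 higher and 104 lower after quantile normalization.

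The list of plaque-associated microglial genes had 14 of 16 tested members higher over all genes and 16 adjusted over the list alone. Beside Cst7, Clec7a, Trem2 and Tyrobp, it held Ccl3, a chemokine, which rose 8.69-fold (log2 change 3.12, SE 0.57), Itgax, which encodes the integrin CD11c and rose 5.59-fold (2.48, SE 0.56), and Cd68, a lysosomal membrane protein of phagocytes, which rose 6.62-fold (2.73, SE 0.52). Apoe, the brain's main lipid carrier, was the most abundant member named here and rose 1.86-fold, from 10664 ± 978 to 20085 ± 4689 (n = 4). The list score, the mean log2 difference of its members from the non-transgenic mean, was 2.16 ± 0.58 in vehicle-treated 5xFAD mice and 0.00 ± 0.11 in non-transgenic mice (SD, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 mice allow; adjusted 0.0548). Limma's fry gave an adjusted p of 0.00316. Camera with an estimated correlation, which asks whether the list moved more than the rest of the panel, gave an adjusted p of 0.353.

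Homeostatic microglial genes, markers of the resting state, were also higher, with 8 of 14 members called and 9 adjusted over the list alone. Csf1r, the receptor for the microglial survival factor, rose 2.67-fold from 984 ± 108 to 2659 ± 589 (n = 4), and P2ry12, a purinergic receptor of resting processes, rose 1.87-fold (log2 change 0.90, SE 0.19). Tmem119, a microglial surface protein, rose 1.52-fold from 608 ± 24.8 to 925 ± 55.5, a call that ended under median centring (log2 change 0.32) and quantile normalization (0.26). The list of pan-microglial and myeloid identity genes had 9 of 12 members higher, 10 adjusted over the list alone, among them the transcription factor Irf8 (3.89-fold), the surface receptor Cd84 (5.09-fold) and the cytoskeletal regulator Dock2 (3.50-fold). Fry gave an adjusted p of 0.00197 for both lists, and camera with an estimated correlation gave 0.353 for both.

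Complement genes rose in 7 of 10 tested members, 9 adjusted over the list alone. C1qc, a subunit of the initiating C1q complex, rose from 1267 ± 188 to 5652 ± 358 (n = 4) and had the smallest adjusted p of all genes, 0.000366 by limma. C1qa rose 4.56-fold, the anaphylatoxin receptor C3ar1 5.35-fold and C4a 4.89-fold, a gene nearly identical to its paralog C4b, with the probe's specificity not given in the sources used here. C3 itself stood at 43.6 ± 25.6 and 92.6 ± 56.0 and was not called (adjusted p = 0.425). In the list of MHC and antigen presentation, 4 of 6 members were higher, 5 adjusted over the list alone. They included the lysosomal protease Ctss (4.94-fold), the immunoproteasome subunit Psmb8 (3.29-fold) and the MHC class II invariant chain Cd74 (4.58-fold, adjusted p = 0.0248), whose call ended without non-transgenic mouse 2 or 4 or 5xFAD vehicle mouse 1 or 4 (adjusted p 0.0527 to 0.071 by limma). Fry gave an adjusted p of 0.00221 for each list, and camera with an estimated correlation gave 0.353 for each.

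Interferon response genes rose in 13 of 21 tested members, 15 adjusted over the list alone. Cxcl10, a chemokine induced by interferon, rose 4.40-fold from 15.8 ± 4.70 to 87.2 ± 54.2 (n = 4). Its non-transgenic mean was also near the Uty and Kdm5d levels of mice with low Y-linked counts, so the size of this fold is uncertain. The nucleic acid sensor Zbp1 rose 3.65-fold (log2 change 1.87, SE 0.34) and Slfn8 3.53-fold (1.82, SE 0.25). Fry gave an adjusted p of 0.00197, and camera with an estimated correlation gave 0.353.

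Fc receptor and phagocytosis genes were higher in 15 of 23 members over all genes and over the list alone, Trem2, Tyrobp and Cd68 among them (fry adjusted p = 0.00221, camera adjusted p = 0.353 with an estimated correlation). Inflammasome, cytokine and chemokine genes were higher in 13 of 23 members, 17 adjusted over the list alone (fry adjusted p = 0.00197, camera adjusted p = 0.353 with an estimated correlation). Ccl3 led them. Casp1, the inflammasome protease, stood at 72.6 ± 34.8 and 153 ± 48.9 (n = 4) and Nlrp3, its sensor, at 28.7 ± 6.45 and 54.7 ± 3.01. Both were called by limma (adjusted p = 0.0303 and 0.045), but Casp1 lost its call in 4 of 8 fits without 1 mouse (without non-transgenic mouse 3 or 4 or 5xFAD vehicle mouse 3 or 4, 0.0505 to 0.101), and Nlrp3 in 7 of 8 (each but the one without non-transgenic mouse 2, 0.0687 to 0.122). Both also lost it under median centring and quantile normalization. Il1b, the cytokine that the inflammasome matures, was not called (31.1 ± 9.02 and 49.9 ± 20.3; adjusted p = 0.251). Toll-like receptor and NF-kB genes were higher in 6 of 25 members, 7 adjusted over the list alone, with Tlr2 at 4.21-fold. Fry called that list (adjusted p = 0.0163), but not after median centring (0.436), nor with camera's preset correlation (0.27) or an estimated correlation (adjusted p = 0.735 with an estimated correlation).

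Among the astrocyte lists, that of genes shared by reactive astrocytes had 4 of 9 members higher, over all genes and over the list alone, including the oncostatin M receptor Osmr (3.47-fold) and the intermediate filament Vim, which rose from 593 ± 121 to 2092 ± 1010 (n = 4). Of the A1 label genes, 3 of 9 were higher, 5 adjusted over the list alone, with the proteoglycan Srgn at 3.19-fold. Fry gave an adjusted p of 0.00609 for each. Camera gave 0.449 for each with an estimated correlation, and 0.0763 and 0.058 with the preset correlation. The A2 label list had 2 of 11 members higher and was not called by fry (adjusted p = 0.0716). Fry called it with a minimum of 50 (0.0449) and with Y-linked status as a block (0.0425). It also did so without both mice with high Ttr (0.01) and without 5xFAD vehicle mouse 1 (0.00709). Camera with an estimated correlation on all mice gave an adjusted p of 0.941. Astrocyte identity genes had 1 of 10 higher, the glutamate transporter Slc1a3 (1.29-fold, adjusted p = 0.0282), which lost its call in 5 of 8 fits without 1 mouse (without non-transgenic mouse 1, 2 or 4 or 5xFAD vehicle mouse 2 or 3, 0.0557 to 0.081) and under median centring. Fry gave that list an adjusted p of 0.0476, and camera with an estimated correlation gave 0.799. The fry call ended without any 1 of the same 5 mice (0.0776 to 0.126), and median centring turned the list's mean change from 0.28 to -0.00458.

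TPPU targets lipid epoxide metabolism, and the list of eicosanoid and oxylipin enzymes and receptors had 2 of 10 members higher, over all genes and over the list alone. These were the cholesterol hydroxylase Ch25h (3.50-fold) and the prostaglandin D synthase Hpgds (2.16-fold), whose call ended under quantile normalization. Ptgs2, the inducible cyclooxygenase, stood at 508 ± 232 and 349 ± 139 (n = 4) and was not called (adjusted p = 0.377 by limma). Fry called the list (adjusted p = 0.0233), but not after median centring (0.264) or with a minimum of 50 (0.24). Nor did it without any 1 of 5 mice (non-transgenic 1, 2 or 3, 5xFAD vehicle 2 or 3, 0.0597 to 0.0803) or with mouse number as a replicate block (0.0688). Camera with an estimated correlation gave an adjusted p of 0.799. The list of apoptosis genes and death receptors had 4 of 33 members higher, over all genes and over the list alone, among them Bcl2a1a, a survival gene of myeloid cells (7.68-fold), and the TNF receptor Tnfrsf1a (2.20-fold). Fry called it (adjusted p = 0.0257), while camera with an estimated correlation gave 0.978. The call ended without non-transgenic mouse 3 or 5xFAD vehicle mouse 2, 3 or 4 (0.0516 to 0.0607) and with mouse number as a replicate block (0.0655), and median centring turned its mean change from 0.28 to -0.000986 (adjusted p = 0.102). Ephx2, the gene for TPPU's target, was not analysed here, nor were Ephx1, App, Gfap and Aif1, and Tnf lay under the minimum.

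Of neuronal and synaptic genes, 0 of 33 were called by limma, over all genes or over the list alone, and the mean log2 change of the list was -0.03 (fry adjusted p = 0.748). That mean was above 0 without 5xFAD vehicle mouse 1 (0.07), non-transgenic mouse 2 (0.01) or both mice with high Ttr (0.03). Camera called the list lower with a preset correlation (adjusted p = 0.000209), and not with an estimated correlation (0.354). Of oligodendrocyte and myelin genes 0 of 23 were called either way, yet 22 of the 23 estimates lay below 0, with a mean of -0.36 (fry adjusted p = 0.173). Mal, a myelin proteolipid, stood at 7613 ± 1555 and 5340 ± 1218 (n = 4; adjusted p = 0.0793 by limma, and 0.0469 without non-transgenic mouse 3). After median centring fry called the myelin list (mean -0.64, adjusted p = 0.00854), and on the deposited scale camera called it lower with a preset correlation (7.74e-11), against adjusted p = 0.353 with an estimated correlation. Mouse 1 of the vehicle-treated 5xFAD group, which had high Ttr, had the lowest myelin score, and without it the mean change was -0.16. Growth factor and trophic genes had 3 of 13 members higher, over all genes and over the list alone, with Tgfb1 at 3.39-fold, while the neurotrophin Bdnf stood at 1237 ± 162 and 817 ± 355 (adjusted p = 0.087 by limma, and 0.0165 without 5xFAD vehicle mouse 4). The growth factor list was not called by fry (adjusted p = 0.177), but was called without 5xFAD vehicle mouse 1 (0.00328) and without both mice with high Ttr (0.00917, with camera adjusted p = 0.799 with an estimated correlation on all mice). The list of T, NK, B cell, neutrophil and monocyte markers (2 of 12 higher, fry adjusted p = 0.0708) was likewise called without that mouse (0.0143) and without both mice with high Ttr (0.038, with camera adjusted p = 0.978 with an estimated correlation on all mice). The remaining lists, of endothelial and perivascular (0 of 12 called, fry adjusted p = 0.721), autophagy (1 of 17, 0 adjusted over the list alone, 0.491), DNA damage response (0 of 43, 0.112, 0.0308 without non-transgenic mouse 2, and 0.7 by camera with an estimated correlation on all mice) and epigenetic genes (0 of 56, 0.362), had means between 0.04 and 0.12. After median centring all 4 means were below 0, with fry calling the autophagy (0.0061), DNA damage (0.0136) and epigenetic lists (0.0117) lower. Also below 0 was the endothelial mean without 5xFAD vehicle mouse 4 (-0.05). On the deposited scale, camera with an estimated correlation called neither the autophagy (adjusted p = 0.7) nor the epigenetic list (0.353).

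**Figure D1:**
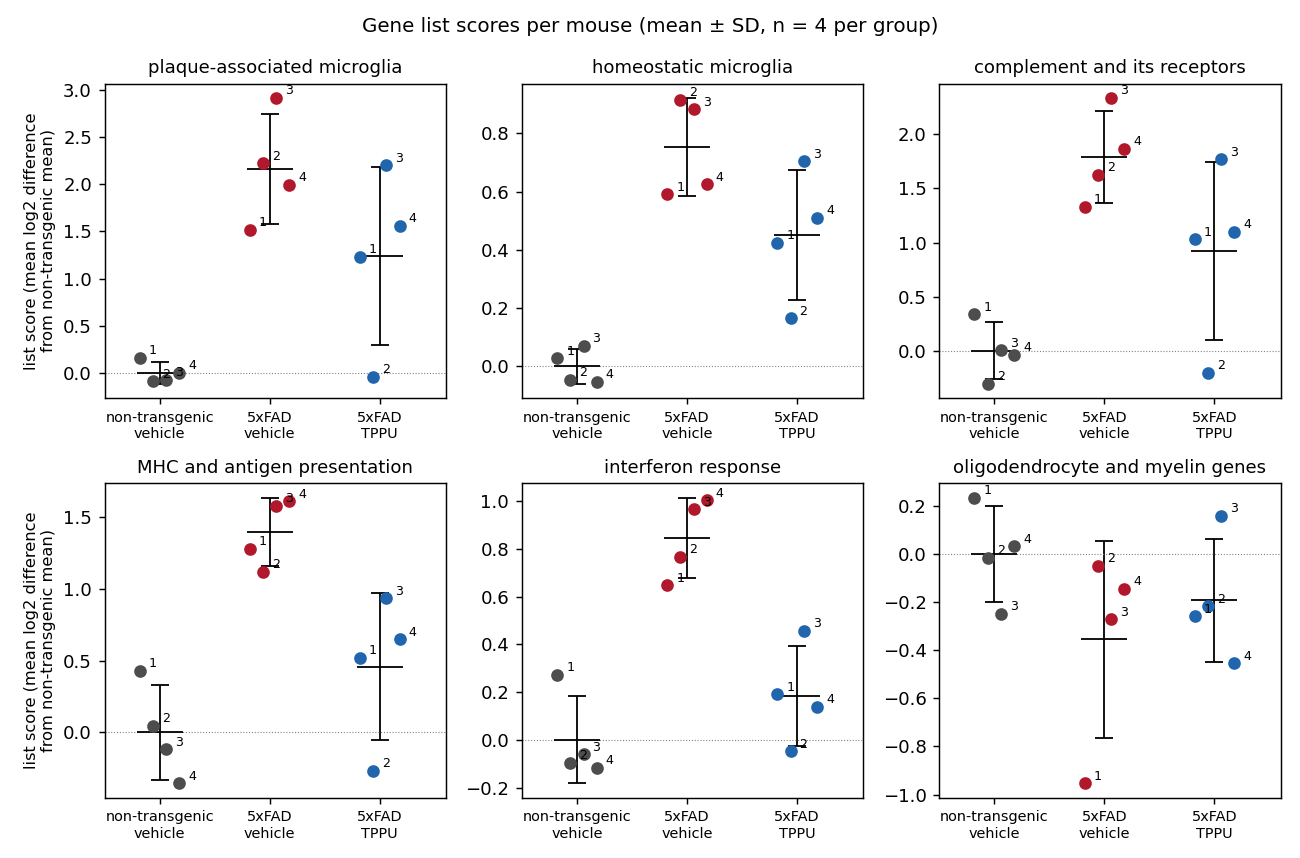
Each panel shows a gene list's score per mouse, the mean log2 difference of its tested genes from the non-transgenic mean, with mouse numbers beside the points and mean ± SD (n = 4 per group) in black. Vehicle-treated 5xFAD mice lie above non-transgenic mice in 5 panels. In the interferon and MHC panels the TPPU-treated mice lie below all vehicle-treated 5xFAD mice. TPPU mouse 2 lies at the non-transgenic level of the plaque-associated list.

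Fry called 14 of 23 lists higher and 0 lower between the genotypes, and camera called 8 higher and 3 lower with a preset correlation of 0.01 and 0 with an estimated correlation. Fry asks whether the genes of a list move on balance 1 way and compares them with no other genes. List scores lay fully apart between the genotypes for 12 of 23 lists. The plot of mean list changes in both comparisons shows each list beside its TPPU value.

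**Figure D2:**
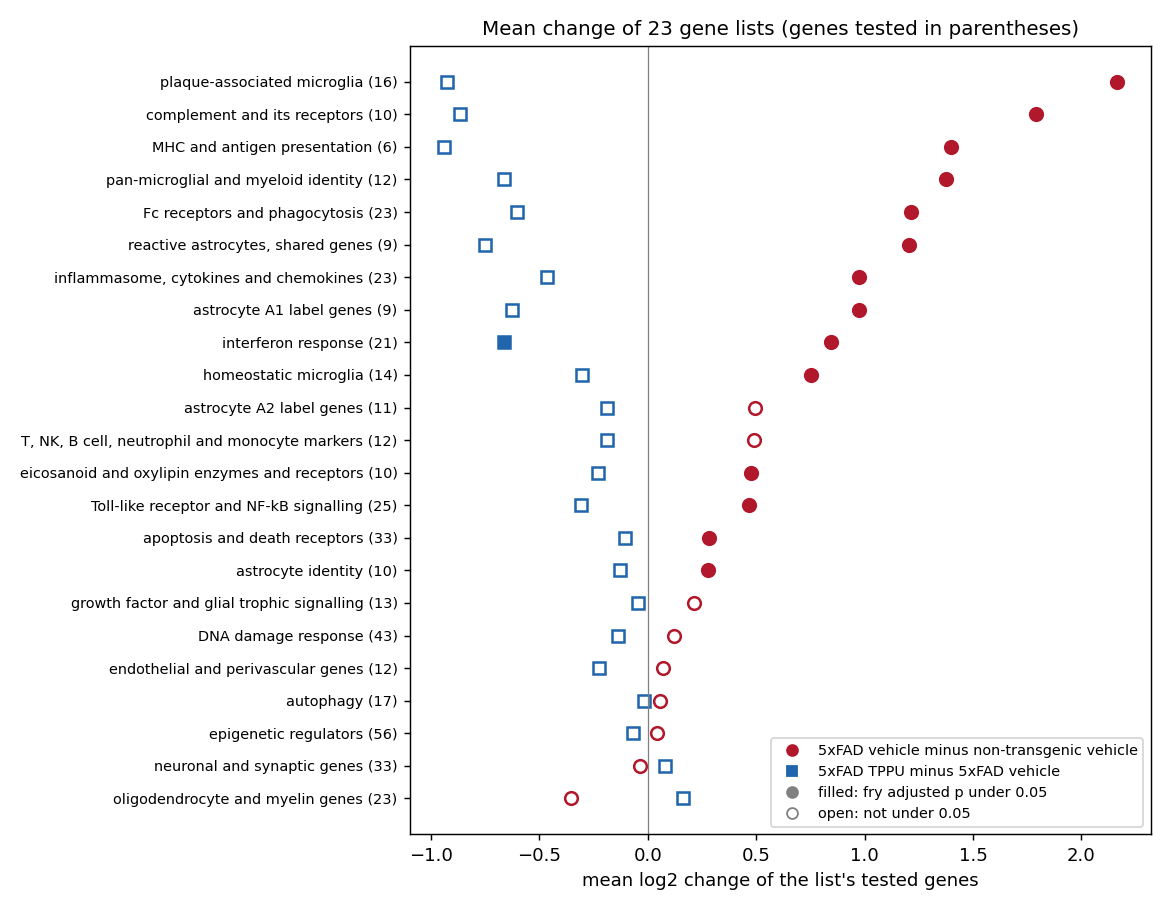
The horizontal axis is the mean log2 change of each list's tested genes (their number in parentheses), as circles for 5xFAD vehicle minus non-transgenic vehicle and squares for 5xFAD TPPU minus 5xFAD vehicle, 4 mice per group, filled where fry's adjusted p is under 0.05. 14 circles are filled and lie above 0, and the interferon response list has the 1 filled square, at -0.66; under median centring the circles of astrocyte identity, apoptosis, autophagy, DNA damage, epigenetic, growth factor and endothelial lists move below 0.

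The comparison of TPPU with vehicle within 5xFAD mice asked whether inhibiting the hydrolase lowers this inflammatory expression. Interferon response genes were lower in TPPU-treated mice as a list, with all 21 estimates below 0 and a mean log2 change of -0.66 (fry adjusted p = 0.0117, camera adjusted p = 0.607 with an estimated correlation). Their score was 0.85 ± 0.17 in vehicle-treated and 0.18 ± 0.21 in TPPU-treated 5xFAD mice, against 0.00 ± 0.18 in non-transgenic mice (SD, n = 4), and all TPPU-treated mice lay below all vehicle-treated ones (exact permutation p = 0.0286, the smallest possible; adjusted 0.164). This separation was not particular to interferon, since the MHC, Toll-like receptor and DNA damage scores were fully apart at the same p. After median centring the interferon and MHC scores stayed fully apart. The Toll-like receptor (exact permutation p = 0.2) and DNA damage scores (0.4) did not. Irf7, the regulator of type I interferon genes, stood at 85.1 ± 17.8 with vehicle and 37.0 ± 11.5 with TPPU, and the RNA sensor Ifih1 at 231 ± 33.6 and 120 ± 16.2. Zbp1 stood at 73.8 ± 18.2 and 27.4 ± 5.38, and Slfn8 at 86.8 ± 4.36 and 42.5 ± 12.6. The TPPU mean of Zbp1 lay within the Uty range of mice with low Y-linked counts (15.2 to 33.5), so the size of its change is uncertain.

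Adjusted over the list alone, limma called 10 of the 21 interferon genes lower, and over all genes it called 0. Fry's unadjusted p for the list was 0.00051. The adjusted p ranged from 4.54e-06 to 0.607 over 16 alternatives, both ends given by camera. Fry no longer called the list without 5xFAD vehicle mouse 3 (0.0534) or with mouse number as a replicate block (0.0524). Within the mice with high Y-linked counts the mean change was -0.82, and within those with low counts -0.50, with 2 mice per group in each.

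**Figure D3:**
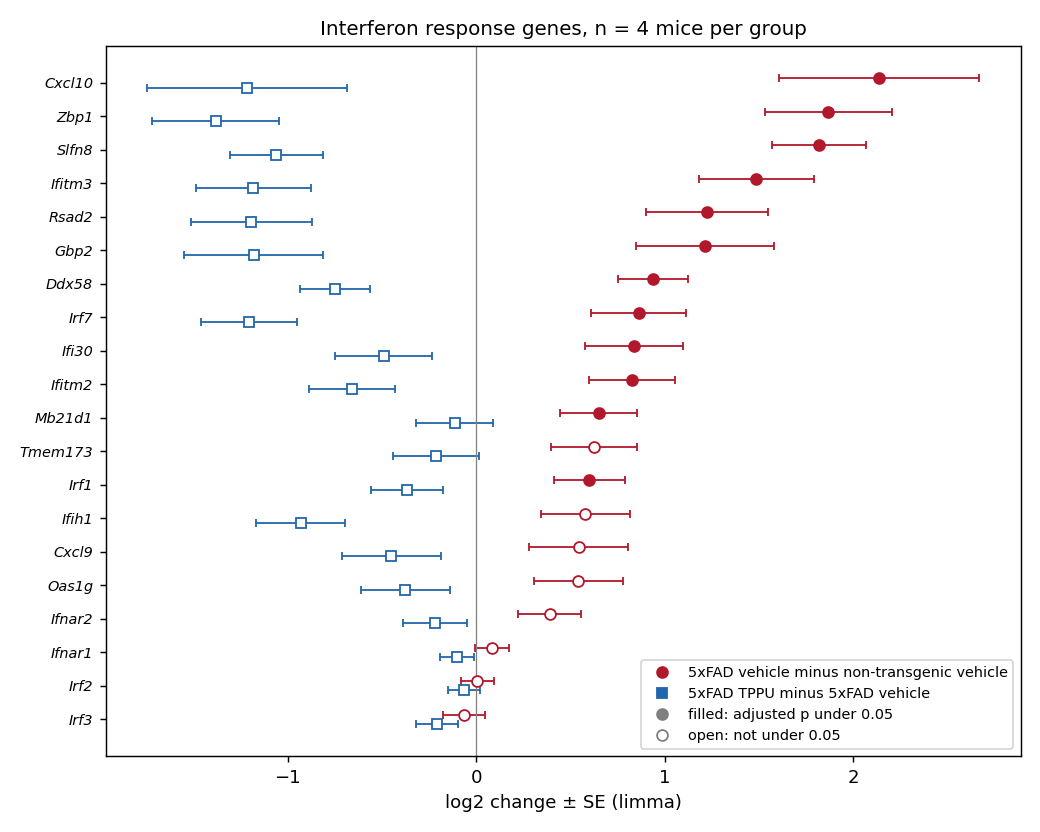
Log2 change ± SE from limma for 20 of the 21 tested interferon response genes, in 5xFAD vehicle minus non-transgenic vehicle (circles) and 5xFAD TPPU minus 5xFAD vehicle (squares), with 4 mice per group and filled points for an adjusted p under 0.05 over all genes. All 20 squares lie below 0 and are open, and 12 circles are filled.

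Single genes did not pass the test between TPPU and vehicle. Limma called 0 of 695 genes, where 126 had an unadjusted p under 0.05, 119 of them lower and 7 higher, and 34.75 are expected by chance; limma with voom weights on the whole probe counts also called 0. The median of all tested genes was -0.12 log2, the array medians differed by -0.20 on average, and the smallest adjusted p was 0.117. C1qc stood at 5652 ± 358 with vehicle and 2748 ± 877 with TPPU (log2 change -1.11, SE 0.22, adjusted p = 0.117 by limma), and C1qb at 4631 ± 1293 and 1982 ± 927 (-1.32, SE 0.32). Cd74 stood at 1049 ± 747 and 193 ± 113, and Psmb8 at 508 ± 82.7 and 238 ± 89.6. Ctse stood at 1005 ± 623 and 147 ± 222 (-3.64, SE 0.77), with TPPU mouse 3 at 479 and the other 3 at 27.7 to 43.2. All 4 TPPU-treated mice lay below all 4 vehicle-treated ones for C1qc, C1qb, Cd74, Psmb8, Irf7, Zbp1, Slfn8 and Ifih1, as in 30 genes altogether, and 4 genes lay fully higher. Chance gives 2.86% of the 695 genes fully apart in both directions together. The genes named were taken by small p in this comparison, so their separation is not independent evidence. Without TPPU mouse 3, limma called 39 genes lower, Ctse (adjusted p = 0.000324), the RNA sensor Ddx58 (0.00972) and C1qc (0.0322) among them; without TPPU mouse 2 or 5xFAD vehicle mouse 2 it called 1. With sample weights limma called 43 genes lower and 1 higher.

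Microglial lists had mean changes below 0 under TPPU but were not called by fry. Camera with a preset correlation called 5 of them lower, the plaque-associated and complement lists (adjusted p = 0.0028 each), the pan-microglial (0.00123), MHC (0.0469) and Fc receptor lists (0.00096), and with an estimated correlation it called none (0.664 for each). The plaque-associated list had a mean of -0.93 (fry adjusted p = 0.136), with scores of 2.16 ± 0.58 with vehicle and 1.24 ± 0.94 with TPPU (n = 4; exact permutation p = 0.171). Trem2 stood at 2405 ± 951 and 1257 ± 797, Cst7 at 273 ± 143 and 111 ± 77.5, and Clec7a at 326 ± 237 and 146 ± 123. Apoe stood at 20085 ± 4689 and 13779 ± 3428. The complement list had a mean of -0.87 (fry adjusted p = 0.0872), with 7 of 10 members lower adjusted over the list alone and 0 over all genes. The MHC list had a mean of -0.94 and the pan-microglial list -0.66, with 2 of 6 and 8 of 12 members lower adjusted over the list alone, and the Fc receptor list had a mean of -0.60, with 0 (fry adjusted p = 0.0814 for each). Homeostatic genes had a mean of -0.30 (0.106), Toll-like receptor genes -0.31 and cytokine genes -0.46 (0.0814 for each). Without TPPU mouse 2 the means of the plaque-associated and complement lists were -0.50 and -0.49 (fry adjusted p = 0.332 and 0.198). Without TPPU mouse 3 fry called 10 lists lower, and without 5xFAD vehicle mouse 1 it called 5.

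Among the lists not named for microglia, the A1 label list had a mean of -0.63 under TPPU (fry adjusted p = 0.0814; -0.41 without TPPU mouse 2), with 5 of 9 members lower adjusted over the list alone, and Srgn stood at 648 ± 187 and 348 ± 134 (n = 4). Its members Psmb8 and Gbp2 also stand in the MHC and interferon lists. RNA of whole hippocampus does not show which cells changed, so an astrocyte change apart from microglia was not shown. The shared reactive astrocyte list had a mean of -0.75 (0.106), and Vim stood at 2092 ± 1010 and 1033 ± 410. The A2 label list had a mean of -0.19 (0.402) and astrocyte identity genes -0.13 (0.304), and both means were above 0 after median centring. Eicosanoid genes had a mean of -0.23 (0.268), while Ptgs2 stood at 349 ± 139 and 579 ± 173 (log2 change 0.76, SE 0.36, adjusted p = 0.282 by limma). Neuronal genes had a mean of 0.08 (0.492), with the postsynaptic scaffold Shank3 at 1635 ± 116 and 2026 ± 255, and myelin genes 0.16 (0.587). Without 5xFAD vehicle mouse 1 both means were below 0 (-0.03 and -0.04). Camera called both lists higher with a preset correlation (adjusted p = 6.14e-06 and 2.31e-05), and neither with an estimated correlation (0.664 each). Bdnf stood at 817 ± 355 and 1138 ± 152. The other lists had fry adjusted p values of 0.274 (endothelial and perivascular), 0.441 (T, NK, B cell, neutrophil and monocyte markers), 0.882 (autophagy), 0.114 (DNA damage response), 0.136 (epigenetic), 0.348 (apoptosis) and 0.805 (growth factor). The T-box factor Eomes, an NK cell and neuronal precursor gene, stood at 15.5 ± 4.63 and 28.3 ± 8.82. It was the 1 gene of the T, NK, B cell, neutrophil and monocyte list higher when adjusted over the list alone. Both its means lay within the Uty range of mice with low Y-linked counts (15.2 to 33.5), so this change is uncertain. Siglecf, an eosinophil and myeloid lectin at 124 ± 48.0 and 53.1 ± 34.1, was the 1 lower in that list. Altogether fry called 1 of 23 lists, where 10 had an unadjusted p under 0.05, and camera called 8 with a preset and 0 with an estimated correlation.

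The question whether TPPU moved the 5xFAD changes back was put to the 130 genes called between the genotypes. All 130 had an estimate of the opposite sign under TPPU, and the median gene moved 51.7% of the way back to the non-transgenic level. Tyrobp, for example, stood at 527, 5251 and 2654 normalized counts in the non-transgenic, vehicle and TPPU groups, and Csf1r at 984, 2659 and 1812. Of the 130, 128 had a higher mean log2 value in TPPU-treated than in non-transgenic mice. Adjusted over these genes alone, limma called 63 lower under TPPU, which is not independent evidence since the list was chosen on the same mice, and over all genes it called 0, with 92 at an unadjusted p under 0.05. That count of 63 was 1 without TPPU mouse 2, 3 without TPPU mouse 1 and 110 without TPPU mouse 3.

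Both changes share the vehicle-treated 5xFAD mice with opposite signs, which alone produces opposite estimates. The correlation of the changes across genes, which are not independent replicates, was -0.85, and groups simulated without any effect gave -0.49 on average (95% of draws between -0.90 and 0.30). With a genotype effect and no TPPU effect, the simulated share of opposite signs averaged 54.3%, with 95.1% as the upper 2.5% limit. In the same draws, simulated medians moved back averaged 0.477%, with 26.4% as the upper 2.5% limit. The measured median of 51.7% was reached in 0 of 200 draws. These draws gave each group the same spread. The SD of the plaque-associated score was 0.11 in non-transgenic, 0.58 in vehicle-treated and 0.94 in TPPU-treated mice, so the simulated limits may be too narrow. When the 4 shared mice were split 2 and 2, so that each change used its own vehicle-treated mice, 84.8% to 100% of the called genes had opposite signs over the 6 ordered splits, and the median moved back was 23.6% to 69.7%, with a mean of 45.8%.

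**Figure D4:**
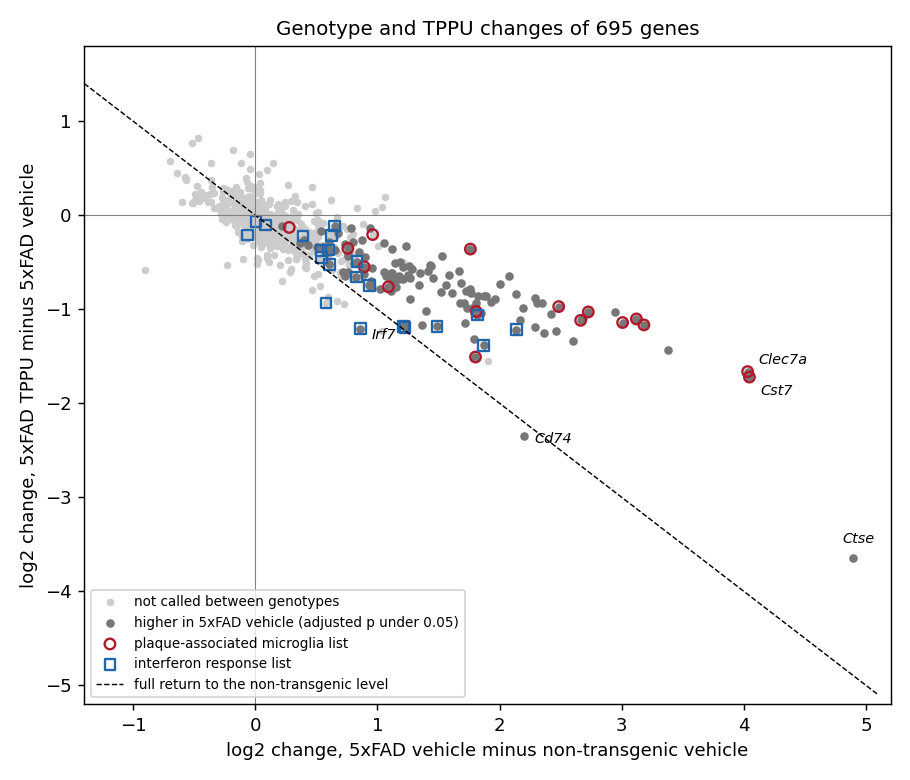
Each point is 1 of 695 genes, with the log2 change of 5xFAD vehicle minus non-transgenic vehicle on the horizontal axis and of 5xFAD TPPU minus 5xFAD vehicle on the vertical axis (4 mice per group), and the dashed line marks a full return to the non-transgenic level. The 130 genes called between the genotypes all lie below 0 on the vertical axis, with mean log2 differences of TPPU-treated from non-transgenic mice of 1.24 for plaque-associated and 0.18 for interferon genes; both axes share the vehicle-treated 5xFAD mice.

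The comparison of TPPU-treated 5xFAD mice with non-transgenic mice asked what remained of the transgene effect under treatment. Limma called 0 of 695 genes, where 102 had an unadjusted p under 0.05, 95 of them higher and 7 lower; the smallest adjusted p was 0.167, and limma with voom weights also called 0. Trem2 stood at 287 ± 63.6 in non-transgenic and 1257 ± 797 in TPPU-treated mice (n = 4), Lag3, an inhibitory receptor, at 90.2 ± 11.5 and 237 ± 106, and the kinase subunit Pik3cg at 38.7 ± 3.40 and 78.4 ± 23.4. Csf2rb, a cytokine receptor subunit, stood at 33.2 ± 4.45 and 57.2 ± 9.69, and the histone methyltransferase Dot1l at 308 ± 17.1 and 235 ± 6.16, both fully apart between the groups. In 43 genes all TPPU-treated mice lay above all non-transgenic mice and in 6 below, where chance gives 2.86% of genes in both directions together. The plaque-associated list had a mean of 1.24 (fry adjusted p = 0.163), with 9 of 16 members higher adjusted over the list alone, and the interferon list a mean of 0.18 (0.435), with 0. Interferon scores of single TPPU-treated mice ran from -0.05 in mouse 2 to 0.46, so this mean also depends on single mice. Fry called 0 of 23 lists, where 5 had an unadjusted p under 0.05, and camera called 10 with a preset and 0 with an estimated correlation. With the preset, camera called the myelin (adjusted p = 6.9e-06), endothelial (0.00224), DNA damage (0.016) and epigenetic lists (0.000606) lower than the rest of the panel. The remaining calls were higher. TPPU mouse 2, whose plaque-associated score was -0.04 against 1.23 to 2.20 in the other 3, decided the gene count: without it limma called 60 genes, Trem2 and Tyrobp among them (adjusted p = 0.00182 each). With sample weights limma called 52 genes higher and 3 lower.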

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

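The tests of TPPU mouse 2, the lower calls and the interferon list address patterns seen first, so none is independent of these data. Among them, those of exchanged labels, total count, panel median, array scaling and high Y-linked counts were chosen after the results were seen. Within each group of 4 mice, the list scores and the named genes were checked for a mouse far from its group; 9 of 231 checks found one, where chance alone gives about 1 in 20, or 11.55.

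Ctse was low in non-transgenic mouse 3 (17.9 against 31.4 to 33.4 normalized counts) and high in TPPU mouse 3 (479 against 27.7 to 43.2). Non-transgenic mouse 1 stood apart with C1qa at 1186 (others 903 to 931), Tgfb1 at 158 (others 120.1 to 125) and an interferon score of 0.27 (others -0.12 to -0.06). Tnfrsf1a stood at 704 in 5xFAD vehicle mouse 3 (others 463 to 478). The neuronal list score was -0.36 in 5xFAD vehicle mouse 1 (others 0.03 to 0.11) and -0.17 in TPPU mouse 3 (others 0.10 to 0.15), and the growth factor score was -0.19 in 5xFAD vehicle mouse 1 (others 0.32 to 0.38). The genotype change of Trp73 differed by -4.20 log2 between mice with high and low Y-linked counts (interaction in limma, adjusted p = 0.0151), with 158 and 34.4 normalized counts in non-transgenic and 5xFAD vehicle mice with high Y-linked counts and 23.7 and 101 in those with low counts, 2 mice each.

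The genotype count of 130 genes was reached by 1 of 35 splits of the 8 mice, the real one, and the highest other split gave 2. That argues against chance only down to 1 in 35, the smallest share these splits allow. It does not bear on other differences between the groups, such as array scaling. For TPPU against vehicle the real count was 0, so all 35 splits reach it by construction and cannot exclude chance. The highest other split, 5xFAD vehicle mouse 1 with TPPU mice 1, 2 and 4 against the rest, gave 48. It differs from the real groups by an exchange of 5xFAD vehicle mouse 1 and TPPU mouse 3. Why that grouping gave more calls was not tested, nor was an exchange of their labels. For TPPU-treated against non-transgenic mice the real count was likewise 0, which all 35 splits reach, the highest other split gave 4, and chance cannot be excluded.

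TPPU mouse 2 lay at the non-transgenic level of the plaque-associated list, at -0.04 against 1.23 to 2.20 in the other TPPU-treated mice. An exchange of labels with a non-transgenic mouse is argued against, since no non-transgenic mouse scored above 0.159 and no vehicle-treated 5xFAD mouse below 1.52. Too few counts are argued against by its total of 1070611, above the lowest other of 1050334. Fewer microglia than in its group stay open: its homeostatic score of 0.165 was above the non-transgenic range (-0.05 to 0.07), the wrong bound since the other 7 5xFAD mice stood higher, at 0.42 to 0.91. A mouse without the transgenes cannot be told apart from a strong response to TPPU: its mean change over the genotype-called genes was 0.0349, within the non-transgenic range of -0.10 to 0.18, and no transgene probe was analysed here.

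Genes were called lower in vehicle-treated 5xFAD mice after median centring (88) or quantile normalization (104) and not on the deposited scale. Whether the rise of immune genes on the panel moved the median of each array stays open: centring on the epigenetic, DNA damage and autophagy genes left 2 lower calls, but these genes moved by only 0.07 on average, so that test decides little. Centring on the median of the 552 genes outside the 10 immune lists left 36 lower calls, fewer than 88 but not few, and the array medians of those genes still differed by 0.19, against 0.28 for all genes. A real loss of myelin RNA stays open and cannot be told apart from the state of 1 mouse: without 5xFAD vehicle mouse 1 the mean change of the myelin list was -0.156 (SE 0.16), so the list rests in part on that mouse.

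For the lower interferon list under TPPU, 4 possible sources were examined, and the values bear on them unequally. Median centring left the list at -0.460 (SE 0.08), which follows from the array median shift of -0.20 seen before. A shift of that size therefore does not account for the whole change. Leaving out TPPU mouse 2 left the list at -0.585 (SE 0.13), which argues against that mouse alone. With each mouse's plaque-associated score as a covariate it was -0.466 (SE 0.12), and the lists share 0 genes. Since a score measured with error takes out only part of what it tracks, a microglial share is not excluded. Mice with high Y-linked counts numbered 2 in each group, which was known beforehand, so their number does not differ between the groups. A fall of interferon response transcripts under TPPU may be proposed only as a hypothesis, found and tested on the same 8 mice and not called by camera with an estimated correlation (adjusted p = 0.607; 4.54e-06 to 0.607 over 16 alternatives).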

How the results depend on the processing

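Chosen after seeing the data were voom weights, Y-linked status as a block, fits without both mice with high Ttr and centring on 3 gene lists; the cause of the changes below was not tested, except where fewer mice were fitted. The total of 130 genes called between the genotypes stayed within 1.5-fold in all 23 alternatives (97 to 190), but only 102 of the 130 were called after median centring and 80 after quantile normalization; the share of opposite signs under TPPU (93.1% to 100%) and the median moved back (36.8% to 64.2%) stayed within 1.5-fold in all 27, where the 6 splits of the shared mice entered as their mean. Single splits gave 84.8% to 100% and 23.6% to 69.7%. The rescaling to housekeeping genes was not run.

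Genes called lower between the genotypes, 0 on the deposited scale, were 88 after median centring, 104 after quantile normalization and 2 after centring on the epigenetic, DNA damage and autophagy genes, and 0 to 1 without 1 mouse (1 without non-transgenic mouse 3 or 5xFAD vehicle mouse 4). For TPPU against vehicle, sample weights gave 44 genes and fits without 1 mouse 0 to 39 (39 without TPPU mouse 3, 1 without TPPU mouse 2 or 5xFAD vehicle mouse 2). For TPPU-treated against non-transgenic mice, sample weights gave 55 and fits without 1 mouse 0 to 60 (60 without TPPU mouse 2). The 63 genes lower under TPPU adjusted over the genotype-called genes alone were 37 after median centring, 13 after quantile normalization, 106 with sample weights, 31 with Y-linked status as a block, 25 after centring on the 3 lists and 12.3 on average with the shared mice split. Without 1 mouse they were 1 to 110: 1, 3 and 32 without TPPU mouse 2, 1 and 4, 110 without TPPU mouse 3, 11 and 28 without 5xFAD vehicle mouse 3 and 2, and 34, 29, 31 and 28 without non-transgenic mice 1 to 4.

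Camera with an estimated correlation called 0 lists between the genotypes and 0 between TPPU and vehicle. For TPPU against vehicle camera's preset correlation called 8 lists (2 higher, 6 lower), Y-linked status as a block 3 and the fit without both mice with high Ttr 3. With mouse number as a replicate block fry called 0, and the interferon list had an adjusted p of 0.0524 (4.54e-06 to 0.607 over 16 alternatives). Between the genotypes that block ended the calls of the eicosanoid (0.0688) and apoptosis lists (0.0655); the genotype count with that block was 125. The numbers were not taken to pair the mice, since only 6 of 12 same-number correlations exceeded 0.1 (-0.37 to 0.39), but what they mark is not given, so a pairing is not ruled out. Without 1 mouse fry called 0 to 10 lists (0 without 5xFAD vehicle mouse 3, 5 without 5xFAD vehicle mouse 1, 10 without TPPU mouse 3). List scores fully apart between TPPU and vehicle went from 4 to 2 after median centring.

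Between the genotypes, directions reversed after median centring for epigenetic (adjusted p = 0.0117), autophagy (0.0061), DNA damage (0.0136), apoptosis (0.102) and astrocyte identity genes (0.989). Endothelial (0.177) and growth factor genes (0.386), not called before or after, also turned below 0. Camera, which compares a list with the rest of the panel and not with 0, placed lower than that rest the epigenetic (0.00629 preset) and apoptosis genes (0.957 preset, 0.978 estimated), and with the preset endothelial (0.175), autophagy (0.16), DNA damage (0.194) and growth factor genes (0.502), all with mean changes above 0. Over all 16 alternatives the first 5 lists ranged from 0.00629 to 0.695, 0.0061 to 0.866, 0.0136 to 0.7, 0.00328 to 0.978 and 0.00459 to 0.989 in that order. Low counts left 61 of 756 genes, Tnf among them, under the minimum and untested.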

Other observations

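All tests in this part were chosen after the data were seen. Mice with high Y-linked counts, 2 in each group, differed from those with low counts in 3 genes by limma: Uty (log2 4.21), Kdm5d (4.20) and Hspb1, a small heat shock protein, which was higher by 1.22 (adjusted p = 0.0386), where 32 genes had an unadjusted p under 0.05. The TPPU change differed between them for 0 genes by limma (smallest adjusted p = 0.805), where 31 had an unadjusted p under 0.05. The plaque-associated list changed between the genotypes by 2.37 log2 in mice with high and 1.95 in mice with low Y-linked counts, and the myelin list by -0.34 and -0.37, with 2 mice per group in each; these differences between lists were not tested.

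With the interferon score as a covariate, the plaque-associated list had a mean TPPU change of 0.73 and was not called (limma's fry, unadjusted p = 0.29).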
